A study of Mus musculus with 6 samples.

How the data were processed

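Chromatin immunoprecipitation followed by hybridisation to promoter tiling arrays (ChIP-chip) was measured in undifferentiated R1 cells, a mouse embryonic stem cell line, grown without feeders and with leukemia inhibitory factor, per the labels. Antibodies raised against SMAD1/5, SMAD2 or SMAD4 were used, with 2 arrays per antibody that carry different probes of 1 promoter set. The 6 arrays were grouped by the antibody and array number in their titles. The series' design text gives 1 biological replicate per antibody, so every comparison rests on single arrays, no value has a replicate check and no p-value is given. On all 6 arrays the immunoprecipitate was labelled with Cy5 (red) and whole cell extract DNA, the input, with Cy3 (green), per the labels. There was no dye swap, so a dye effect cannot be separated from enrichment.

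The deposited scanner files give an intensity per spot and channel, as mean signal, local background and processed signal. Per the file headers, the processed intensity was background-subtracted, detrended over the array and dye-normalised by Agilent Feature Extraction. The SMAD1/5 and SMAD2 arrays were extracted with version 9.1.3.1 and a copy number protocol, and the SMAD4 arrays with version 9.5.3.1 and a ChIP protocol, per the file headers. Extraction and antibody therefore cannot be told apart for SMAD4. The deposited files also hold other columns, per-spot flags of 0 or 1 for spots well above background, saturated or outlying, set by the same software per the file headers. The deposited value tables hold the authors' log2 values, which correlated positively with log2 red over green of the same array (r from 0.74 to 0.95 over probes). Limma is named for them in the submitters' processing notes without a version or a list of steps. From that match the direction is immunoprecipitate over input. The medians of the authors' log2 columns were 0.08 and -0.01 for SMAD1/5, 0.05 and 0.04 for SMAD2, and -0.0047 and -0.0022 for SMAD4. Their exact centring stays unknown, and so does their scale, since the slope against the scanner ratio ran from 0.44 to 0.90. They were used as an alternative only.

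Each array held 237195 or 237185 probes, 1 spot each, with a median spacing of 183 or 182 bp. Spots with an outlier flag in either channel were left out, between 0.0084% and 0.019% of probes on the SMAD1/5 and SMAD4 arrays and 1.06% and 1.82% on the SMAD2 arrays. Saturated spots were kept. The log2 ratio of processed red over processed green was centred on each array's median, with no loess and no scaling between arrays. Each probe's window value was the mean log2 ratio of the probes within 500 bp on the same chromosome, with at least 3 probes. A window z was its distance from the array's median window, divided by a robust SD taken from the windows below that median. A window was called enriched at a z of at least 4 with at least 2 probes above the 95th percentile of single probes. Low windows were called by the same rule turned over. A gene was enriched if a window centred on any of its probes was, and its peak z is the highest z among its windows. These rules, the alternatives planned, the 14 gene lists and the rule for named genes were set before the data were examined.

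Gene names came from the array annotation. Of 17113 names, 16106 were updated through their RefSeq accession in the GRCm38.p6 gene table, 370 matched a symbol, 374 matched a single older symbol, and 263 kept the name in the file. This left 16998 genes, of which 16692 had windows for SMAD1/5 and SMAD4 and 16690 for SMAD2. The genome build of the probe positions is not given in the sources used here. Positions are printed as the array annotation gives them, and the gene table was used for names alone. Distances to transcription start sites are also those of the annotation.

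The rule for named genes was as follows. Every measured gene of the BMP target list and of the Activin, Nodal and TGF-beta target list could be named, with Pou5f1, Sox2, Nanog, Kdm6b and Dpysl2. For each antibody the 10 enriched genes with the highest peak z and a gene symbol were named, then up to 4 enriched members of each other list, and for each pair of antibodies the 5 highest enriched genes whose peak z for the other antibody was under 2. Genes enriched with all 3 antibodies would have been named as well. Nanog, Pmepa1 and Cdkn2b had no windows under their names. Some genes that the rule names are not reported here.

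Calls were set beside low windows and beside 20 shuffles of the probes over positions. In the shuffles z was taken once with the shuffled array's own SD and once at the log2 height of the real threshold. Overlaps were set beside the number shared by independent lists and beside 10000 draws matched on array, number of windows and input. Correlations were computed across windows, which share probes and are not independent replicates, and set beside 200 shifts of 1 array's windows along the probe order. A gene list's median peak z was given as its percentile among 10000 random lists of the same size, matched in the same way, as a description of these arrays. Where an antibody's input or immunoprecipitate is set against the others, the mean of the other antibodies' channel was subtracted. Such a difference can come from any of the arrays compared. The steps were tested on simulated data. Peaks that fell off linearly from their centre over 1000 bp on each side were added on arrays with shifted log ratios. Their height is that of the centre, so they added less than it to a window mean. With a log2 height of 4 in 100 genes of 17016, the rule found 17% of them for SMAD1/5, 95% for SMAD2 and 96% for SMAD4. At log2 height 2 it found 0%, 10% and 19%. Before peaks were added it called 0, 22 and 572 genes on the simulated arrays. Of 100 random lists over 16692 genes (16690 for SMAD2) with nothing added, 12, 6 and 6 passed the 95th percentile for SMAD1/5, SMAD2 and SMAD4. With 1 unit of z added, 100, 100 and 99 did.

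The alternatives chosen in advance were normexp background correction of the mean signals with an offset of 50, loess within each array, the authors' values, windows of 1000 bp on each side, a z of at least 5, a window mean of at least 2-fold, only probes well above background in both channels on all 3 arrays of a design, and removal of a smooth trend of the ratio on the array's own log2 input. The last stands in for a correction on GC content, which needs probe sequences that were not used here. Chosen after seeing the data were removal of a trend on the other antibodies' inputs, the mean input of the 3 arrays as denominator, windows of at least 5 probes, removal of chromosome medians, and overlaps of the 500 genes with the highest peak z. The profiles over start sites and chromosomes were also added after seeing the data. No column of values outside those named was used. Computations used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.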

Results

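The series mapped where SMAD proteins sit on promoters in undifferentiated mouse embryonic stem cells. SMAD1 and SMAD5 carry BMP signals to the nucleus, SMAD2 carries Activin, Nodal and TGF-beta signals, and SMAD4 is the partner shared by both branches. DNA recovered with each of 3 antibodies was hybridised against its own whole cell extract on a pair of promoter arrays, which gave 6 arrays and 1 biological replicate per antibody. Array 1 covers chromosomes 1 to 8 and the start of 9, and array 2 the rest of 9 to 19, X, Y and the mitochondrial genome. The number of arrays limits the precision, and each error below is an SD or SE over probes of 1 array, which does not measure the spread between experiments.

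Signal strength differed between the antibodies' arrays. The median input signal was 2.35 and 2.73 times its local background on the SMAD1/5 arrays, 7.45 and 6.90 times on the SMAD2 arrays, and 5.36 and 5.05 times on the SMAD4 arrays. The share of probes whose input lay well above background was 72.3% and 87.0% for SMAD1/5, 88.5% and 86.1% for SMAD2, and 99.6% and 99.7% for SMAD4. Single-probe log2 ratios had an SD of 1.93 and 1.76 for SMAD1/5, against 0.93 and 0.91 for SMAD2 and 0.99 and 0.98 for SMAD4. A control probe repeated on 480 spots varied far less, with an SD of at most 0.19 on the SMAD1/5 arrays, 0.12 on the SMAD2 arrays and 0.08 on the SMAD4 arrays. These spots hold a single sequence and were well above background in both channels. Their SD therefore does not measure the noise of dim probes.

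The SMAD1/5 arrays address which promoters BMP-responsive SMADs occupy. None of the 20 measured BMP target genes reached the threshold with this antibody, and the highest was Gata3 with a peak z of 1.81. Id1, a classical BMP target, had a peak z of 1.27, with a window mean log2 ratio of 1.33 ± 1.70 (SD over 4 probes) 247 bp inside its start site. Id2 had a peak z of 1.80, Id4 1.64, Id3 0.34 and Smad6, an inhibitory SMAD, 0.94. The median peak z of the BMP list lay at percentile 26.1 of matched random lists. Kdm6b, a histone H3 lysine demethylase, had a peak z of 2.22 at 2.27 ± 0.94 (7 probes), and the neuronal gene Dpysl2 had 1.18.

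Across the genome 0 of 16692 genes were enriched with SMAD1/5, while 439 had a low window, and shuffled probes gave a mean of 0.7 enriched genes. Because the probes scattered widely, a window had to reach a log2 ratio of 4.61 on array 1 and 4.17 on array 2, which is 24.4-fold and 18.0-fold, so binding below that height was not called on these arrays. In the BMP list the low side held Bambi, a decoy receptor of the pathway, at -4.73 ± 1.97 (SD over 5 probes), centred at -299 bp from its start site, and Msx2 at -4.54 ± 3.27 (3 probes). Their inputs lay 4.06 and 3.41 log2 units above the mean of the other antibodies' inputs, while their immunoprecipitates differed by -0.42 and -0.83. These low windows were chosen after their values were seen. The split of enriched to low genes moved with normexp correction to 861 and 2801, and Kdm6b then reached a z of 6.10, Lefty1 4.70 and Pou5f1 4.44. In the authors' values it was 28 and 1299, with Kdm6b at 4.19, and with the mean input of the 3 arrays it was 5 and 32. Without the trend on the array's own input it was 0 and 26.

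The SMAD2 arrays address the Activin and Nodal branch. Of 21 measured genes of that target list, 0 were enriched and 8 had a peak z of at least 2, or 38.1% against 18.4% of all genes, and in the BMP list it was 25%. With SMAD4 the share was 28.6% of the Activin and Nodal list and 35% of the BMP list against 40.2% of all genes, and with SMAD1/5 0% of each against 5.95%. Ski, a repressor of SMAD signalling, was highest at a z of 3.28 with a window mean of 1.89 ± 1.27 (SD over 4 probes), and Junb followed with 2.80. The feedback inhibitor Smad7 had 2.15 and Lefty1 2.10, with a window mean of 1.22 ± 0.04 (3 probes) for Lefty1, while Nodal had 1.64 and Lefty2 0.49. The list's median lay at percentile 88.4 of random lists and ran from 16.3 to 98.3 over the alternatives.

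Genome-wide 11 genes were enriched with SMAD2 and 56 had a low window. The highest peak z were those of Pard3, a cell polarity gene, at 5.52, Shisa7 at 5.43, Hsfy2 at 5.02 and Ilk, the integrin-linked kinase, at 4.92. Cdk14, Psg17, Per1, Slc35e1 and Rfwd3 had peak z from 4.77 down to 4.13. In 7 of the 10 highest genes the SD over the window's probes was at least 2, as in Pard3, whose window mean of 3.15 ± 3.54 held a highest probe of 6.90 and a lowest of -0.14. All probes of the window passed a log2 ratio of 1 in 4 of the 10, among them the clock gene Per1 (2.46 ± 0.55, 4 probes) and Slc35e1 (2.39 ± 0.43, 3 probes). Shuffled probes gave a mean of 54.4 genes when scaled by their own SD and 3.9 at the same log2 height. The count of 11 lies below that of independent probes on 1 scale and above it on the other. Shuffles break the correlation between neighbouring probes, and shifted arrays, which keep it and any real peaks, called 22 genes. In the peak windows of the 10 highest genes the SMAD2 input lay at least 1 log2 unit below the mean of the other inputs in 7. This fall was larger than the rise of the immunoprecipitate in 6. The input differed from that mean by -4.37 at Shisa7, -2.60 at Per1 and -3.20 at Slc35e1, and the immunoprecipitate by 0.34, 0.42 and -1.26. The mean takes in the SMAD1/5 input, so a fall need not be particular to the SMAD2 input. In the same windows the SMAD1/5 z was -2.27 at Shisa7, -0.46 at Per1 and 1.36 at Slc35e1. Shisa7 kept a z of at least 4 in 6 of 6 alternatives run on single genes but did not pass with the mean input of the 3 arrays, while Ilk kept it in 5 and Slc35e1 in 0. The split of enriched to low genes was 5 and 115 in the authors' values, 5 and 517 with the mean input of the 3 arrays, 5 and 9 without the trend on the array's own input, and 2 and 5 with normexp correction, where Shisa7 and Ilk were left.

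**Figure D1:**
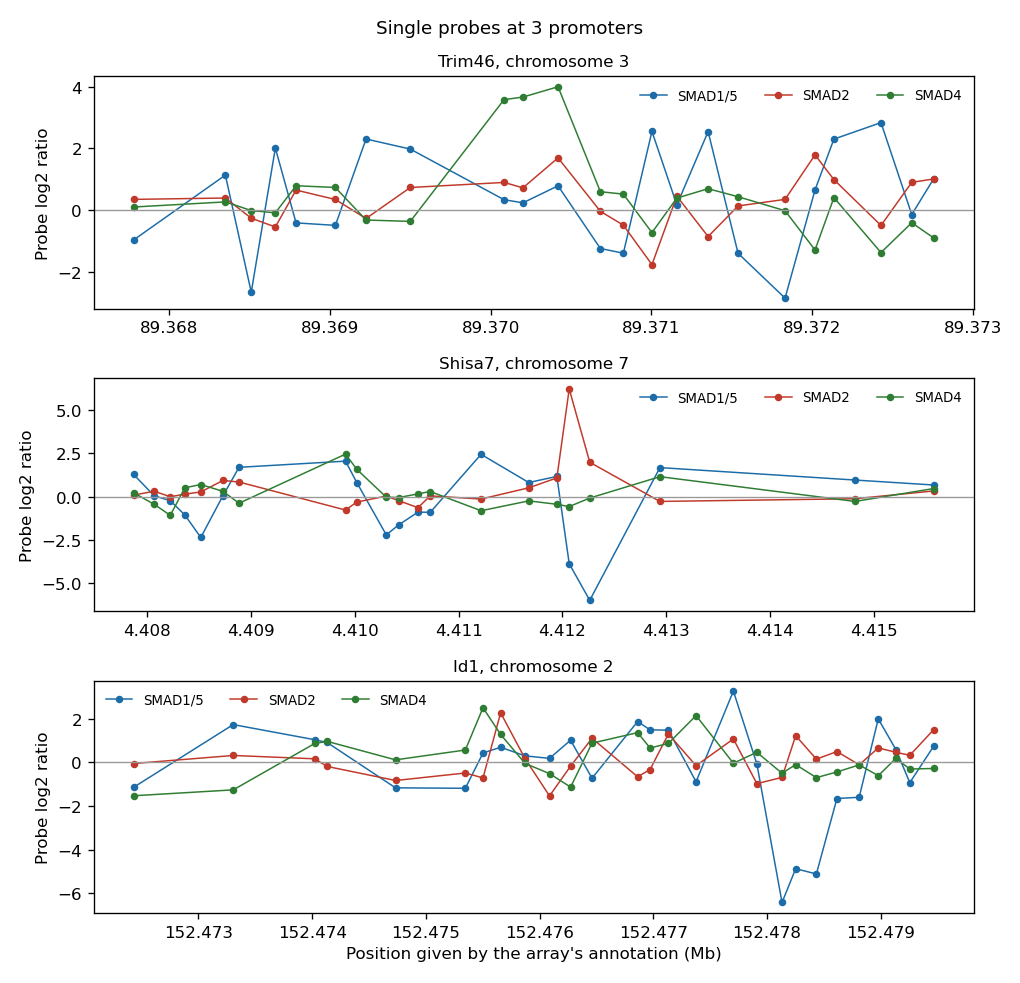
Log2 ratio of immunoprecipitate over input (y axis) for each probe against its position in Mb (x axis) at Trim46, Shisa7 and Id1, with lines in blue for SMAD1/5, red for SMAD2 and green for SMAD4. The SMAD4 peak at Trim46 spans 3 probes between 3.58 and 4.00, and the SMAD2 peak at Shisa7 has probes at 1.08, 6.24 and 1.98.

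The SMAD4 arrays address the shared partner. SMAD4 had the highest peak at Trim46, which encodes a microtubule-associated protein of neurons, with a peak z of 6.58 and a window mean of 3.74 ± 0.22 (SD over 3 probes), on chromosome 3 from 89370060 to 89370449 and 1525 bp inside the start site. The bitter taste receptor gene Tas2r138 followed at a z of 6.08 (3.46 ± 1.64, 4 probes), then Car12, a carbonic anhydrase, at 6.01, and Apln, which encodes the peptide apelin, at 5.91 (3.35 ± 0.54, 3 probes). Olfr1350, Toporsl, Tg, Gimap4, Grpr and Fam78b had peak z between 5.75 and 5.47. Tg encodes thyroglobulin of the thyroid, and was the 1 enriched member among 35 genes of adult tissues. Of the BMP list 1 of 20 genes was enriched, the BMP antagonist Grem1, with a z of 4.04 and a window mean of 2.33 ± 0.50 (6 probes) at -1506 bp from its start site. Msx2 had 3.87, or 4.30 with bright probes only, Dlx5 3.44, Id4 3.06 and Id1 2.46, while Id2 had 1.21, Id3 0.71 and Bambi 0.64. Of the Activin and Nodal list 0 of 21 passed. Bmp2 passed among 24 pathway components with a z of 4.20, and the X-linked demethylase gene Kdm6a among 27 chromatin regulators with 4.55. Bmp2 and Kdm6a kept a z of at least 4 in 0 of 6 alternatives and Grem1 in 1, against 4 for Trim46 and 5 for Tg.

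In all, 416 of 16692 genes (2.49%) were enriched with SMAD4 and 8 had a low window. Shuffled probes gave a mean of 268.7 genes scaled by their own SD and 35.9 at the same log2 height. Shifted arrays, which keep the correlation between neighbouring probes and any real peaks, called 572. Peaks lay within 1000 bp of a start site in 74 of the 416 genes, or 17.8%, against 25.2% of all genes. The 416 held 35 of 807 olfactory receptor genes, led by Olfr1350, Olfr95, Olfr456 and Olfr874, and 65 of 577 genes on X. In 702 of 807 enriched windows (87.0%) the central probe was among the 20% of probes with the lowest SMAD4 input, and 35.3% had only 3 probes against 15.1% of all windows. In the peak windows of the 10 highest genes the SMAD4 input lay at least 1 log2 unit below the mean of the other inputs in 10. The immunoprecipitate lay at least 1 above the mean of the others in 3, which were Trim46, Tg and Fam78b. For Bmp2, Kdm6a and Grem1 the input differed from the others by -2.23, -3.89 and -2.32 log2 units and the immunoprecipitate by 0.44, -0.98 and 0.04. After removal of the ratio's trend on its own input 3 genes passed, Spink2, Trim46 and Matk, against 303 with a low window, and with the mean input of the 3 arrays Trim46 and Farp1 passed, against 187. The array's own input is also the ratio's denominator, and after removal of the trend on the other antibodies' inputs 462 genes passed, 414 of them among the 416, against 6. That trend cannot remove lows particular to the SMAD4 input. Spink2, Matk and Farp1 were chosen after their values were seen. The split was 162 and 29 with loess.

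The pairs of antibodies address whether SMAD4 shares promoters with either branch. No gene was enriched with more than 1 antibody, where independent lists of 11 and 416 genes would share 0.27. With SMAD1/5 the overlap was fixed at 0, since it had 0 enriched genes. The 10 highest SMAD4 genes had peak z with the other antibodies on either side of the median gene, which had 1.35 with SMAD2 and 1.26 with SMAD1/5. Apln had 0.62 with SMAD2 and 1.26 with SMAD1/5, Tas2r138 0.78 and 1.29, Car12 1.86 and 1.62, Olfr1350 2.24 and 1.35, and Grpr 1.26 and 2.46, while Toporsl had 2.45 with SMAD2. These are the highest values anywhere in each gene. In the window of the SMAD4 peak they were -0.87 and 1.12 for Apln, -0.20 and 0.04 for Tas2r138, and -0.39 and 0.80 for Car12. For Olfr1350 they were 1.28 and 1.35, for Grpr -0.08 and 1.96, and for Toporsl 0.33 and -3.08. Trim46 had 1.34 with SMAD1/5 and 1.89 with SMAD2, the latter in the window of its SMAD4 peak. Of the SMAD2 genes, Hsfy2 had 3.94 with SMAD4, Pard3 2.73, Cdk14 2.69 and Per1 2.68, while Slc35e1 had 0.50 and Rfwd3 -0.31, against a median of 1.74. In the windows of their SMAD2 peaks the SMAD4 z was lower, at 0.86 for Hsfy2, 0.81 for Pard3, 2.57 for Cdk14 and -1.18 for Per1. For Slc35e1 and Rfwd3 it was -1.25 and -0.90. Among the 500 genes with the highest peak z of each antibody, SMAD2 and SMAD4 shared 20 where matched draws gave a mean of 12.0, and 183 of 10000 draws gave as many. SMAD1/5 and SMAD4 shared 13, with a mean of 12.6 in draws, and SMAD1/5 and SMAD2 shared 36, with a mean of 16.4 and a highest draw of 34. Genes of a divergent promoter share windows, which the matching of the draws does not keep, so draws may understate the overlap without shared binding. SMAD1/5 and SMAD2 also shared an extraction version and protocol.

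Across windows, the z of SMAD2 and SMAD4 correlated with Pearson's r of 0.094 and Spearman's rho of 0.101, SMAD1/5 and SMAD2 with 0.043 and 0.048, and SMAD1/5 and SMAD4 with 0.029 and 0.029. Shifted arrays gave r between -0.011 and 0.012 over the 3 pairs. These are correlations across windows of single arrays, and windows are not independent replicates. The immunoprecipitate channels correlated with each other at r of 0.86 (SMAD2 and SMAD4), 0.67 (SMAD1/5 and SMAD4) and 0.63 (SMAD1/5 and SMAD2), and the inputs at 0.61, 0.44 and 0.50. With the trend on the array's own input removed, r of the window z rose to 0.43, 0.28 and 0.21 in the same order of pairs. That input is also the ratio's denominator, so this removal can leave values that lean on the immunoprecipitate channels, which correlate by themselves. The rise therefore cannot speak for shared binding. With normexp correction r of SMAD1/5 and SMAD2 was -0.085.

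Of 42 medians, for 14 gene lists and 3 antibodies, 3 lay above percentile 95 of random lists and 7 below percentile 5. In the simulation, lists with nothing added passed percentile 95 in 12, 6 and 6 of 100 cases for SMAD1/5, SMAD2 and SMAD4. They fell below percentile 5 in 5, 2 and 5, so some of these calls can arise by chance. The 807 olfactory receptor genes, silent outside sensory tissue, had medians at percentile 0 with each antibody and in each of 6 alternatives. Their median peak z was 0.86 against 1.22 in random lists for SMAD1/5, 0.52 against 1.17 for SMAD2 and 1.68 against 2.08 for SMAD4. With SMAD4 their enriched share was 4.34% against 2.49% of all genes, but this comparison was not matched on windows or input. The 82 ribosomal protein genes lay at 99.8 with SMAD2 and at 2.28 with SMAD4. Genes of adult tissues lay at 98.2 with SMAD4, where Tg was the enriched member. Ectoderm and neural genes lay at 0.235 with SMAD4 and 2.98 with SMAD1/5, trophectoderm genes at 1.06 and cell cycle genes at 96.8 with SMAD1/5. In SMAD1/5 the trophectoderm call held in 0 of 6 alternatives, the cell cycle call in 2 and the neural call in 3.

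The remaining medians lay between percentiles 5 and 95, though not in every alternative. The pluripotency list of 31 genes was at 67.6, 35.0 and 5.49 for SMAD1/5, SMAD2 and SMAD4, with Sox2 at peak z of 1.37, 1.96 and 1.38 and Pou5f1 at 1.14 with SMAD1/5 and 0.67 with SMAD4. The Hox list was at 54.9, 58.1 and 10.4, and mesoderm and endoderm genes at 66.6, 77.7 and 12.4. With SMAD4 these lists stayed between 5 and 95 in only 2 of 6 alternatives each, and fell as low as 0.835 and 1.53. WNT, FGF and Notch genes were at 70.2, 45.9 and 16.2, chromatin regulators at 90.2, 35.5 and 21.4, and pathway components at 86.4, 60.3 and 46.2. The BMP list was at 73.3 with SMAD2 and 7.58 with SMAD4, and the Activin and Nodal list at 77.2 with SMAD1/5 and 34.9 with SMAD4. Trophectoderm genes were at 63.1 with SMAD2 and 32.1 with SMAD4, cell cycle genes at 73.7 and 12.8, neural genes at 51.8 with SMAD2, ribosomal protein genes at 87.7 with SMAD1/5, where 1 of 6 alternatives stayed below 95 and the highest was 99.9, and adult tissue genes at 32.7 with SMAD1/5 and 12.1 with SMAD2.

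**Figure D2:**
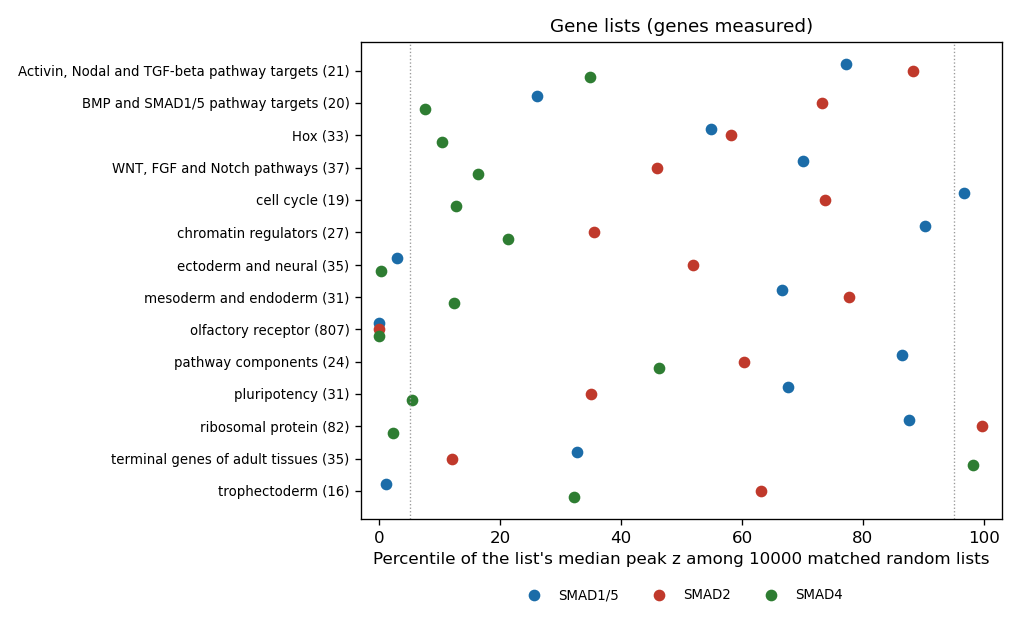
Percentile of each gene list's median peak z among 10000 matched random lists (x axis) for 14 lists with the number of measured genes in brackets (y axis), in blue for SMAD1/5, red for SMAD2 and green for SMAD4, with dotted lines at 5 and 95. Olfactory receptor genes sit at 0 for all 3 antibodies, and ribosomal protein genes at 99.8 for SMAD2 and 2.28 for SMAD4.

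Around transcription start sites the mean log2 ratio followed a different course for each antibody. With SMAD1/5 it was -0.59 within 250 bp of a start site and -0.29 at 2000 to 4000 bp upstream on array 1, a difference of -0.30 ± 0.016 (SE over probes), and the difference was -0.49 ± 0.014 on array 2. With SMAD4 the difference was -0.20 ± 0.008 on each array. With SMAD2 it was 0.08 ± 0.007 and 0.07 ± 0.007. The input itself rose towards start sites by 0.81 to 1.15 log2 units, and the immunoprecipitate by 0.61 to 0.89. The mean difference for SMAD1/5 turned to 0.13 when the trend on its own input was removed (0.27 on array 1 and -0.0058 on array 2) and to 0.08 with normexp correction. For SMAD4 it turned to 0.07 without that trend. For SMAD2 it turned to -0.18 with normexp correction and to -0.08 with the mean input of 3 arrays.

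**Figure D3:**
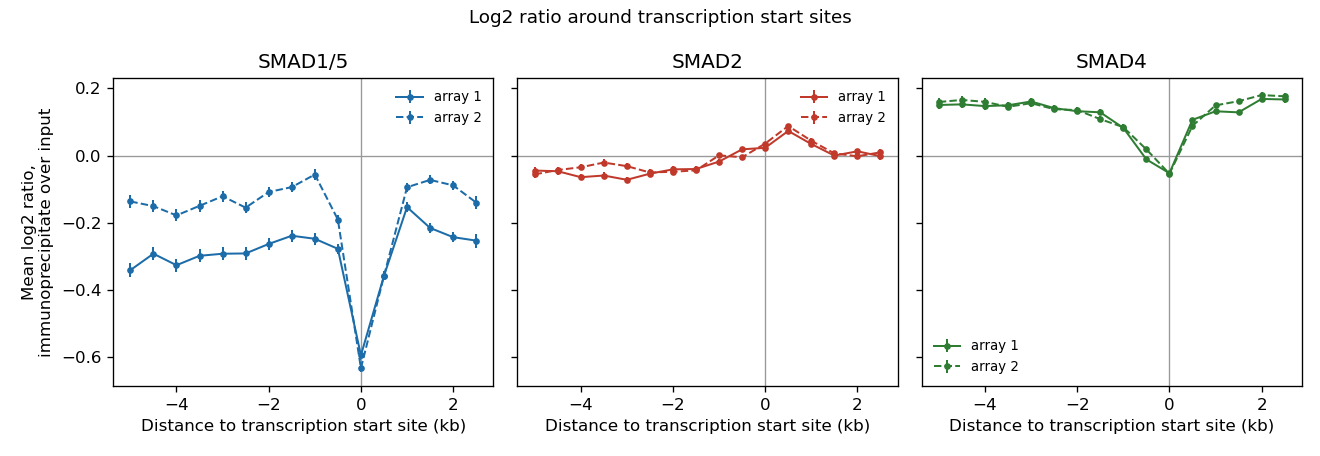
Mean log2 ratio of immunoprecipitate over input (y axis) in steps of distance to the transcription start site in kb (x axis), for array 1 (solid) and array 2 (dashed) of each antibody, with SE over probes as bars. SMAD1/5 falls to -0.59 and -0.63 at the start site, SMAD4 to -0.05 on each array, and SMAD2 stays near 0.

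Whole chromosomes stood apart in the log2 ratio of the SMAD1/5 arrays. The median log2 ratio was 0.40 on chromosome 8 (22484 probes), 0.28 on chromosome 11 (38349 probes) and -0.58 on X (17335 probes), where the other autosomes lay between -0.12 and 0.11. With SMAD2 these chromosomes had 0.02, 0.06 and -0.10, and with SMAD4 -0.01, -0.01 and 0.07. The same chromosomes stood apart in the input of every antibody. Chromosome 8 had the highest median log2 input of array 1, at 7.93, 9.46 and 10.44 for SMAD1/5, SMAD2 and SMAD4. On array 2 chromosome 11 was the highest autosome (9.21, 9.43 and 10.56) and X the lowest chromosome (8.00, 8.11 and 8.61). The input of SMAD1/5 lay below that of SMAD4 on chromosomes 8 and 11, with medians of -0.44 and -0.40, and above it on X by 0.71, while it differed from the SMAD2 input by -0.08, -0.03 and -0.02. The SMAD1/5 immunoprecipitate differed from that of SMAD2 by 0.17, 0.13 and -0.34, where other autosomes ran from -0.15 to 0.19, and from that of SMAD4 by -0.07, -0.12 and 0.19. SMAD2 differed from SMAD4 in both channels, by -0.28, -0.32 and 0.63 in the input and -0.23, -0.23 and 0.51 in the immunoprecipitate. On Y (204 probes) the ratio was -0.31 with SMAD1/5 and -0.23 with SMAD4, and SMAD1/5 lay above SMAD4 by 0.78 in the input and 0.82 in the immunoprecipitate (134 probes). Id1, Bambi and Msx2 lie on other chromosomes, and Kdm6b lies on chromosome 11. The median on chromosome 8 was 0.11 in the authors' values and 0.17 with loess, and that on X -0.14 and -0.13.

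**Figure D4:**
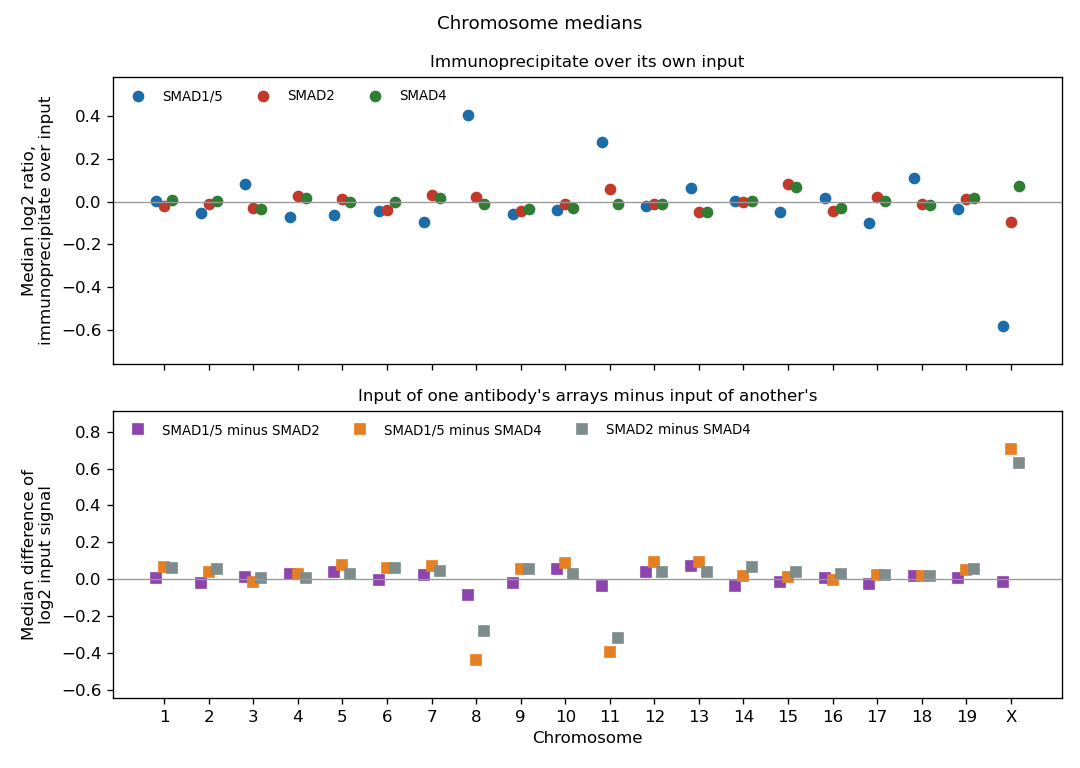
Median log2 ratio of immunoprecipitate over input per chromosome for each antibody (upper panel), and median difference of log2 input signal between pairs of antibodies (lower panel), with chromosomes on the x axis. SMAD1/5 stands at 0.40 on chromosome 8, 0.28 on chromosome 11 and -0.58 on X, and both other inputs differ from the SMAD4 input on these 3 chromosomes. The lower panel uses only probes well above background on all 3 arrays of a design.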

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

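Tests chosen only after the result was seen were those of chromosome content, low input spots, probes falling together by chance, SMAD2 values in SMAD4 windows, and the SMAD1/5 input at start sites. The start site and chromosome profiles were chosen after seeing the data as well.

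The start site difference went 1 way on both SMAD1/5 arrays and the other way on both SMAD2 arrays, a gap of -0.47 log2 units in the mean of 2 arrays, and SMAD4 stood apart from SMAD2 in the same way by -0.27. With normexp correction SMAD4 stood at -0.043 and SMAD2 at -0.18, so the gap between SMAD4 and SMAD2 changed sign. Neither gap was tested, nor any biological explanation of it, since antibody and input changed together with 1 replicate per antibody, and for SMAD4 the extraction as well. Dim spots alone do not account for the SMAD1/5 fall, since it was -0.47 with bright probes. But normexp correction, which acts most on spots near background, turned it to 0.08 and the SMAD2 value to -0.18, so their gap changed sign as well. The trend of the ratio with signal strength stays open: its removal on the array's own input left 0.13, but that input is also the denominator of the ratio, and removal of the trend on the other arrays' inputs left -0.28. A higher SMAD1/5 input at start sites cannot be told apart from the rest either, because its excess over the other inputs of 0.24 came to at least 0.5 of the fall on array 1 (0.26) and to less on array 2 (0.22).

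Mitochondrial probes, which carry no gene name and entered no gene count, had a median log2 ratio of 0.38 with SMAD1/5 (47 probes), 1.21 with SMAD2 (43) and 1.71 with SMAD4 (47). They were kept when array 2 was centred and its windows were formed. The SMAD1/5 input lay 1.77 log2 units above that of SMAD4 here and 3.03 above that of SMAD2. In the immunoprecipitate it was 0.69 and 2.17. These probes were picked out as a signal outside the main measurement, and the differences were not tested.

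The chromosome shifts of SMAD1/5 held along whole chromosomes: 43 of 43 bins of 10 Mb, or 100%, lay above the median on chromosomes 8 and 11 and below it on X, against 46.1% above among 228 bins of other autosomes. A trend on the array's own input does not account for them, since chromosomes 8, 11 and X stayed at 0.37, 0.33 and -0.63 after its removal, with other autosomes between -0.09 and 0.02, but loess, which acts on overall intensity, brought them to 0.17, 0.22 and -0.13, so part of the shift depends on the correction. Nor does binding at promoters account for the shift of chromosome 8, since it would leave a weaker shift far from start sites. That shift was 0.45 over 2000 bp away against 0.38 within 1000 bp. Chromosomes 11 and X were not tested in this way. A candidate explanation, as a hypothesis, is that the SMAD1/5 immunoprecipitate and its input came from cultures of different chromosome content: on 8, 11 and X its input lay near that of SMAD2 (-0.08, -0.03 and -0.02) and apart from that of SMAD4 (-0.44, -0.40 and 0.71), while its immunoprecipitate lay nearer to SMAD4 on these chromosomes (-0.07, -0.12 and 0.19, with other autosomes from -0.09 to 0.16) than its input did, though not on Y (0.82 against 0.78). It was found and tested on the same arrays, the immunoprecipitate stood outside the other autosomes (-0.15 to 0.19) against SMAD2 only on X (-0.34), not on 8 (0.17) or 11 (0.13), and a karyotype of the cultures would test it. The SMAD1/5 and SMAD2 arrays also shared an extraction version and protocol that the SMAD4 arrays did not. An input near that of SMAD2 and apart from that of SMAD4 therefore cannot be told apart from the extraction.

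The SMAD4 genes sat where the SMAD4 input was low: in their windows it lay -2.24 log2 units from the mean of the other inputs, while the immunoprecipitate was 0.11 above the mean of the others. Low spots of that input may therefore account for most of the calls, and 2 genes passed with the mean input of the 3 arrays. After removal of the trend on the other arrays' inputs 462 passed. That trend cannot remove lows particular to the SMAD4 input, so this count does not bear on them. Single high probes that vary independently and fall together by chance do not account for all of them. Shuffles gave 47.3 windows at the same height and 399 at the shuffled arrays' own SD, against 807. But shuffles break the correlation between neighbouring probes (0.41 and 0.42 on the SMAD4 arrays), so they speak only to independent probes. Shifted arrays, which keep that correlation and any real peaks, called 572 genes against 416. Regions bound by SMAD complexes stay open, since the median SMAD2 z in the enriched SMAD4 windows was 0.079 and that of SMAD1/5 0.176, near 0, and SMAD4 with other partners was not measured.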

How the results depend on the processing

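No paired analysis was possible because each antibody has 1 replicate. The alternatives with other arrays' input, mean input, 5 probes and chromosome medians, the overlap of 500 genes, and all alternatives for start sites and chromosomes were chosen after seeing the data. Where a value moved, the cause was not tested, except that a stricter z or more probes per window calls fewer genes by construction.

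Genes enriched with SMAD1/5, SMAD2 and SMAD4 numbered 861, 2 and 52 with normexp correction and 28, 5 and 83 in the authors' values. The mean input of the 3 arrays gave 5, 5 and 2, and a 2-fold window mean gave 3145, 2432 and 3677, with 4857, 3064 and 2238 genes low by the same measure. Loess gave 11 for SMAD1/5 and 162 for SMAD4. SMAD2 and SMAD4 had 3 and 51 at a z of at least 5, 5 and 3 without the trend on own input, and 1 and 128 with at least 5 probes. Windows of 1000 bp gave 18 for SMAD2. The genes of counts of up to 5, chosen after their values were seen, were for SMAD2 Shisa7 and Ilk (normexp), these with Hsfy2, Gpat4 and Uap1 (authors' values), Pard3, Shisa7 and Hsfy2 (z of 5), Shisa7, Ilk, Pard3, Hsfy2 and Cdk14 (own input), Ilk (5 probes), and Cdk14, Hdac11, Mr1, Uso1 and Cyp2b9 (mean input). For SMAD1/5 the mean input left Nrk, Sh3d21, Grpr, Smarcc2 and Rgs2, and for SMAD4 Trim46 and Farp1. Without the trend on own input SMAD4 kept Spink2, Trim46 and Matk. The other counts stayed within 1.5 times. With loess 161 of the 162 SMAD4 genes, with the authors' values 70 of 83, and with bright probes 172 of 335 were among the 416. For SMAD2 only 2 of the 12 genes with bright probes and 5 of the 18 with 1000 bp windows were among the 11, so a similar count can hold other genes.

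Shared genes were 5 for SMAD1/5 and SMAD4 with normexp correction (Alox12, Cd7, Spata31d1a, Spink2 and Tns4) and 1 for SMAD2 and SMAD4 with bright probes (Cog2). With a 2-fold window mean the pairs SMAD1/5 and SMAD4, SMAD2 and SMAD4, and SMAD1/5 and SMAD2 shared 749, 549 and 689, against means of 738, 541 and 514 in matched draws, of which 2875, 3363 and 0 of 10000 gave as many. Among the 500 highest genes they shared 13, 20 and 36. The matched draws do not keep windows shared by genes of a divergent promoter. In every other alternative run the count was 0. For pairs with SMAD1/5 it was fixed at 0 wherever no gene was enriched with that antibody. Elsewhere independent lists would share at most 0.30, so these counts say little about shared promoters.

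The correlation of window z in the same order of pairs was 0.104, 0.074 and -0.085 with normexp correction, 0.039, 0.201 and 0.030 in the authors' values, 0.030, 0.068 and 0.0063 with bright probes, and 0.276, 0.430 and 0.215 without the trend on own input. For the pairs with SMAD4 it was 0.053 and 0.207 with loess and 0.024 and 0.121 with windows of 1000 bp. Without chromosome medians it was 0.035 for SMAD1/5 and SMAD4. These moved by more than the gap between both array designs.

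The start site difference turned for SMAD1/5 to 0.0815 with normexp correction and 0.13 without the trend on own input, for SMAD2 to -0.18 with normexp correction and -0.0805 with the mean input, and for SMAD4 to 0.0706 without the trend on own input. Without turning, it shrank for SMAD1/5 to -0.13 with loess and -0.12 in the authors' values. For SMAD4 it shrank to -0.077 with loess, -0.079 in the authors' values and -0.043 with normexp correction. For SMAD2 it rose to 0.15 with loess, 0.13 in the authors' values and 0.21 without the trend on own input. The chromosome medians of SMAD1/5 kept their sign in 7 of 7 alternatives, from 0.11 to 0.38 on 8, 0.09 to 0.33 on 11 and -0.63 to -0.13 on X. Of 26 enriched named genes 22 passed with loess, 14 with 1000 bp windows, 11 in the authors' values, 6 without the trend on own input and 4 with normexp correction. With bright probes 5 of the 23 that could be measured passed. Signal over background was lowest for the SMAD1/5 input, at 2.35 and 2.73 times. On these arrays simulated peaks of log2 height 4 at their centre were found in 17% of genes, which limits what the absence of calls can show.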

Other observations

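The genes and regions here were chosen after their values were seen. Upstream of Lefty2, a Nodal target that inhibits the pathway, the ratio was low with 2 antibodies. With SMAD2 the lowest window was -2.50 ± 0.84 (SD over 4 probes) on chromosome 1 from 180867862 to 180868696, and with SMAD4 it was -2.74 ± 0.28 (5 probes) from 180868211 to 180868933, centred at -4531 and -4235 bp from the start site. The SMAD2 input lay 1.38 log2 units above the mean of the other inputs, and the SMAD4 input 3.11 above the mean of its others. The immunoprecipitates lay 0.23 and 1.32 above the means of theirs. Each mean takes in the SMAD1/5 array, so a low SMAD1/5 input there can give part of both input values. They do not show that the SMAD2 input lay above the SMAD4 input. Upstream of Eomes, a mesendoderm regulator, SMAD1/5 had its lowest window of the Activin and Nodal list at -5.71 ± 1.72 (5 probes), with an input 6.23 log2 units above the others. Tdgf1, the Nodal co-receptor, had a low window with SMAD2 at -2.17 ± 0.70 (5 probes), where its input and immunoprecipitate differed from the others by -0.24 and -0.31.

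Low windows with SMAD1/5 were not concentrated at start sites: the lowest window lay within 1000 bp of one in 98 of 439 such genes, or 22.3%, against 36.9% of all genes.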
